A study of Escherichia coli with 10 samples.

How the data were processed

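Total RNA from E. coli BL21(DE3) with a dCas9 and mCherry plasmid and 1 of 5 guide plasmids was sequenced in 10 libraries, 2 per guide. Per the labels' protocols, cells grew in LB medium with chloramphenicol and spectinomycin, were induced with anhydrotetracycline and were treated with an RNA-stabilising reagent. RNA was extracted on columns with DNase, rRNA was depleted with Ribo-Zero plus, and libraries were made with a stranded kit. The submitters' processing notes name FastQC, Bowtie and SAMtools without versions or roles. The values are FPKM, fragment numbers scaled by gene length and library size, made by the authors with Cufflinks, per the file headers, on sequence CP001509.3. The version and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. In 1232 of 4336 rows the file gave a gene less than all reads of its locus in at least 1 library, so such genes are uncertain. The comparisons were planned for TPM. The files held FPKM, and the fallback to that unit, written before the data were examined, was used.

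The files list 4336 genes by locus tag, with 22 rRNA and 85 tRNA rows as judged from the tag. All 22 rRNA rows were at 0 in every library. The files do not pair the tags with gene names, and 0 of 4336 tags matched the reference table of another strain, so no gene is named. The 46 gene lists fixed before the data were examined could therefore not be tested, and neither could the target gene, because no plasmid gene is in the files used here.

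Depth was derived from the confidence bounds, which lie 2 SD above and below FPKM, so a gene's implied fragment number is the square of 2 times FPKM over the distance to the upper bound. Implied fragments on genes came to 7329323 to 13255977 per library. Of implied numbers below 500, 22.2% were whole within 0.02, against 4% by chance, so whole reads were not recovered and no count test was run. Between 46.4% and 56.2% of genes with at least 20 implied fragments differed between replicates beyond counting noise, so no library was treated as a duplicate. Intervals on fragments cover counting error only.

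rRNA and tRNA rows were left out, libraries were scaled by median-of-ratios factors (0.958 to 1.07), and 3937 of 4229 genes with a mean of at least 1 FPKM were tested. The value tested was log2(FPKM + 1), so fold changes of genes with low values are understated. A linear model with the 5 groups was fitted to all 10 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the moderation and 5 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within each of 7 comparisons, two-sided, at 0.05. Figures were drawn with matplotlib 3.10.9. Values printed with ± are mean ± SD over 2 libraries on scaled FPKM or log2(FPKM + 1).

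The rule for printed genes, fixed before the data were examined, took the 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap between groups. At most 2 tags per direction and comparison are printed because no names could be given. Among those 10, genes under 200 bp or below 1 FPKM in any of the libraries compared were passed over, a limit chosen after the data were seen. The regions, defined as at least 3 neighbouring tested genes on one strand with the same direction, and the 3 with the largest median change per direction, were also chosen after the data were seen, as was the 2-gene locus. Calls were shuffled 1000 times over genes for the number of genes in regions.

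The test was tested on simulated data for sg_WT against sg_PC with 3937 genes and 200 changed. The changed genes were drawn from those with a mean of at least 5 FPKM, so recovery below that mean is not covered. Noise was normal and independent between genes, with the fitted variance taken as true. The test found 76% of 100 genes changed by 1 on the log2 scale and 95% of 100 changed by 2, with 7 calls among 3737 unchanged genes. Alternatives were FPKM without scaling, pseudocounts of 0.1 and 5, no filter, a mean of at least 10 FPKM, a replicate block, only the 2 groups compared, precision weights on coverage, no trend, and each library left out. Added after the data were seen were genes of at least 200 bp, removal of the trend with gene length, and genes that share no reads.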

Results

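RNA sequencing was done on Escherichia coli BL21(DE3), a laboratory strain used for protein production, carrying a CRISPR interference system. In this system a nuclease-dead Cas9 is guided by a single guide RNA (sgRNA) and blocks transcription where it binds. Cells held 1 plasmid with dCas9 and mCherry, a red fluorescent protein gene that the series names as the target, and 1 plasmid with a guide. The 10 libraries fell into 5 groups of 2 by guide plasmid, named sg_PC, sg_WT, sg_trcSL1c2, sg_trcSL1c5 and sg_trcSL1c10. The series asks about off-target effects of guide variants, so each other guide was compared with sg_PC, and each trcSL1c guide also with sg_WT. The labels do not state what the abbreviations mean or which group is the reference. The files list chromosomal genes of sequence CP001509.3 and no plasmid gene, so the level of mCherry was not analysed here. The confidence bounds in the files implied a depth of 9629296 to 17277667 fragments per library, and the median gene had 257 to 463 implied fragments.

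Expression differed widely by guide plasmid. Of 3937 genes tested, 2296 differed among the 5 groups (limma moderated F test, adjusted p below 0.05). The first principal component held 39.2% of the variance. It set sg_WT at one end, with scores of 37.8 and 40.9, and sg_trcSL1c5 at the other, with -25.6 and -24.0. The sg_trcSL1c10 libraries lay between, at 14.1 and 8.62, and the sg_PC libraries at -10.3 and -9.59. The sg_trcSL1c2 replicates lay further from each other, at -8.70 and -23.2, with replicate 1 near sg_PC and replicate 2 near sg_trcSL1c5 on this component. The second component held 16.1% and separated sg_PC, at 27.4 and 24.97, from sg_trcSL1c2, at -19.6 and -20.1. Replicates correlated across genes at r = 0.966 to 0.978, and libraries of different groups at 0.904 to 0.965. Genes are not independent replicates. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

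**Figure D1:**
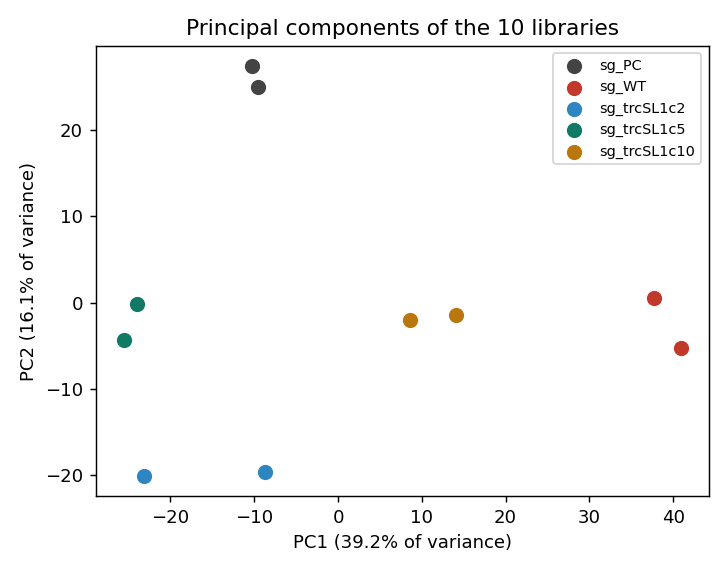
Scores of the 10 libraries on the first and second principal components of log2(FPKM + 1), with 2 points per guide group. The sg_WT libraries lie at 37.8 and 40.9 on the first component and the sg_trcSL1c5 libraries at -25.6 and -24.0.

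**Figure D2:**
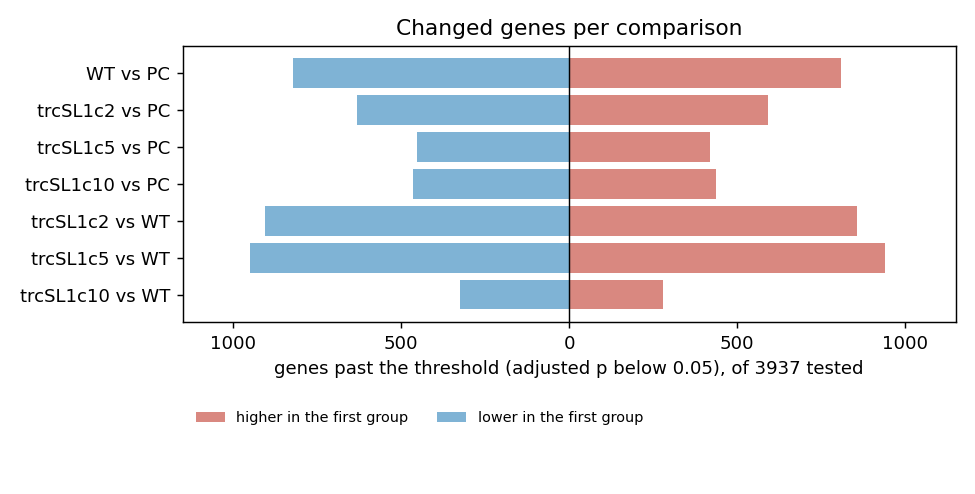
Number of genes higher (right) and lower (left) in the first group of each comparison, of 3937 tested, at an adjusted p below 0.05. The bars range from 279 genes higher in sg_trcSL1c10 than in sg_WT to 950 genes lower in sg_trcSL1c5 than in sg_WT.

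Between sg_WT and sg_PC, the largest rises in sg_WT were in separate regions of the chromosome. A plus-strand region of 3 genes at 3777526 to 3781586 had a mean of 8.02 ± 0.40 log2(FPKM + 1) in sg_WT and 4.43 ± 0.05 in sg_PC (SD, n = 2). Its 3 genes rose unevenly, by 0.82, 4.87 and 5.07. A minus-strand region of 6 genes at 1769553 to 1776395 stood at 8.01 ± 0.34 against 3.82 ± 0.21. Another region of 3 genes, at 4154156 to 4157846, rose by a median of 3.45 on the log2 scale. Among regions that fell, minus-strand genes at 2958033 to 2961808 (4 genes) had a median log2 change of -3.46 and those at 2953898 to 2957069 (3 genes) of -3.22. Plus-strand genes at 3773289 to 3775518 (3 genes) had a median of -2.31. The only gene among them that shares no reads with an overlapping gene changed by -1.28. The gene ECD_03592, in the first region, had 3939 ± 1349 FPKM in sg_WT and 113 ± 11.8 in sg_PC, a log2 change of 5.07 (SE 0.31, limma adjusted p = 5.67e-05). ECD_01717 rose by 4.93 (SE 0.37, limma adjusted p = 9.62e-05). ECD_02826 had a log2 change of -3.78 (SE 0.79, limma adjusted p = 0.00604) and ECD_02825 of -3.78 (SE 0.55, limma adjusted p = 0.00104). The call of ECD_02826 was lost without sg_WT replicate 2, at an adjusted p of 0.0511. The files do not pair these tags with gene names.

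In all, 810 genes were higher and 821 lower in sg_WT than in sg_PC, and 717 of these 1631 changed at least 2-fold. Genes that lay in runs of at least 3 neighbours on one strand, all changed in the same direction, numbered 593. The median of 1000 shuffles of the calls over genes was 96. The shuffle treats neighbouring genes as independent, but neighbours may share a transcript or reads. The excess is therefore not a result about the guides. The region at 2953898 to 2957069 lay near 0 in sg_WT, where its mean was 0.44 ± 0.10 (SD, n = 2). Its change moved with the settings, to -1.52 with a pseudocount of 5 and to -4.98 with precision weights. In the region at 1769553 to 1776395, genes that shared reads with an overlapping gene made up all but 1. These genes, ECD_01713 to ECD_01717, rose by 4.39 to 4.93. The remaining gene rose by a log2 change of 1.68, a value that does not correct the others for shared reads. ECD_01716 ends at 1775178 and ECD_01717 starts at 1775175, so they overlap by a few bases only.

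In sg_trcSL1c2 the largest rise against sg_PC was in 2 adjacent minus-strand genes at 2605462 to 2607664. ECD_02490 had 1556 ± 21.3 FPKM in sg_trcSL1c2 and 75.4 ± 0.35 in sg_PC (SD, n = 2). The log2 change was 4.35 (SE 0.09, limma adjusted p = 1.20e-07), a 20.4-fold difference. ECD_02489 beside it rose from 98.7 ± 1.36 to 838 ± 48.3 FPKM, a log2 change of 3.07 (SE 0.10, limma adjusted p = 3.92e-06). The 6-gene region at 1769553 to 1776395 was also higher, by a median of 1.86, but its level differed between the sg_trcSL1c2 replicates, at 6.34 and 5.17 log2(FPKM + 1), a mean of 5.76 ± 0.82 against 3.82 ± 0.21 in sg_PC (SD, n = 2). Also higher were 3 genes at 4445117 to 4448004, by 1.54, and 9 genes at 4499318 to 4509196, by 1.41. Among regions that fell, 3 genes at 2163703 to 2167131 changed by a median of -1.30, 3 at 2807943 to 2809770 by -1.23 and 3 at 1852953 to 1854274 by -1.23. In the last of these, ECD_01795 went from 495 ± 124 to 54.4 ± 10.4 FPKM (limma adjusted p = 0.000491). The region's median was -2.19 without its genes under 200 bp. ECD_03557 had 53.6 ± 1.48 FPKM in sg_PC and 5.83 ± 3.24 in sg_trcSL1c2 (limma adjusted p = 0.000735).

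The comparison counted 592 genes higher and 630 lower, 382 of them at least 2-fold. Without sg_PC replicate 1 or replicate 2 the total of 1222 became 698 or 760, and with only the groups compared in the fit it was 599.

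In sg_trcSL1c5 the same 2 adjacent genes were among the largest rises against sg_PC. ECD_02490 reached 1996 ± 60.4 FPKM (log2 change 4.71, SE 0.09, limma adjusted p = 6.43e-08) and ECD_02489 1035 ± 56.7 FPKM (log2 change 3.38, SE 0.10, limma adjusted p = 1.87e-06). Other regions that rose were 3 plus-strand genes at 371030 to 372730 (median 2.00), 3 at 2665798 to 2667699 (median 1.73) and 3 at 4063302 to 4066524 (median 1.26). Regions that fell were 3 genes at 1355391 to 1356369 (median -1.78), 3 at 1527888 to 1534823 (median -1.29) and 3 at 754495 to 756145 (median -1.22). ECD_02248 had 2422 ± 254 FPKM in sg_PC and 236 ± 34.3 in sg_trcSL1c5 (log2 change -3.36, SE 0.20, limma adjusted p = 0.000152). ECD_03485 went from 52.6 ± 21.4 to 4.50 ± 1.01 FPKM (limma adjusted p = 0.0165), and this call was lost with a pseudocount of 0.1, where the adjusted p was 0.128. It was also lost without sg_PC replicate 1 and without either sg_trcSL1c5 library.

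This comparison had 420 genes higher and 454 lower, of which 215 changed at least 2-fold. The total of 874 became 300 or 446 without sg_PC replicate 1 or 2, and 330 or 497 without sg_trcSL1c5 replicate 1 or 2.

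In sg_trcSL1c10 the 2 adjacent genes rose against sg_PC too. ECD_02490 had 1152 ± 10.5 FPKM (log2 change 3.92, SE 0.09, limma adjusted p = 2.75e-07), and the gene beside it had a log2 change of 3.09. ECD_03592, which also rose in sg_WT, had 1558 ± 19.0 FPKM (log2 change 3.78, SE 0.31, limma adjusted p = 0.00107). The region at 1769553 to 1776395 rose by a median of 2.84, that at 4154156 to 4157846 by 2.26, and 5 genes at 3564018 to 3569859 by 2.04. The region at 3773289 to 3775518 (3 genes) fell, with a median of -1.57, 3 genes at 3259543 to 3262243 had a median of -1.18, and 3 genes at 758657 to 759786 of -1.50. ECD_10018, in that last region, went from 90.7 ± 24.1 to 11.1 ± 10.9 FPKM (limma adjusted p = 0.00800), and ECD_01871 from 64.4 ± 46.3 to 10.1 ± 4.87 FPKM (limma adjusted p = 0.0171). Both calls were lost with only the groups compared in the fit and without sg_PC replicate 2, and that of ECD_01871 also without sg_trcSL1c10 replicate 2. In the region at 1769553 to 1776395, ECD_01714 to ECD_01717, which share reads, rose by 2.76 to 2.92. The only gene there that shares no reads with an overlapping gene changed by 1.05. In the region at 3773289 to 3775518, the only such gene changed by -0.82.

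Here 437 genes were higher and 465 lower, 265 of them at least 2-fold. The total of 902 became 448 or 383 without sg_PC replicate 1 or 2, and 372 or 428 without sg_trcSL1c10 replicate 1 or 2. On FPKM without scaling the split was 544 higher and 364 lower.

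**Figure D3:**
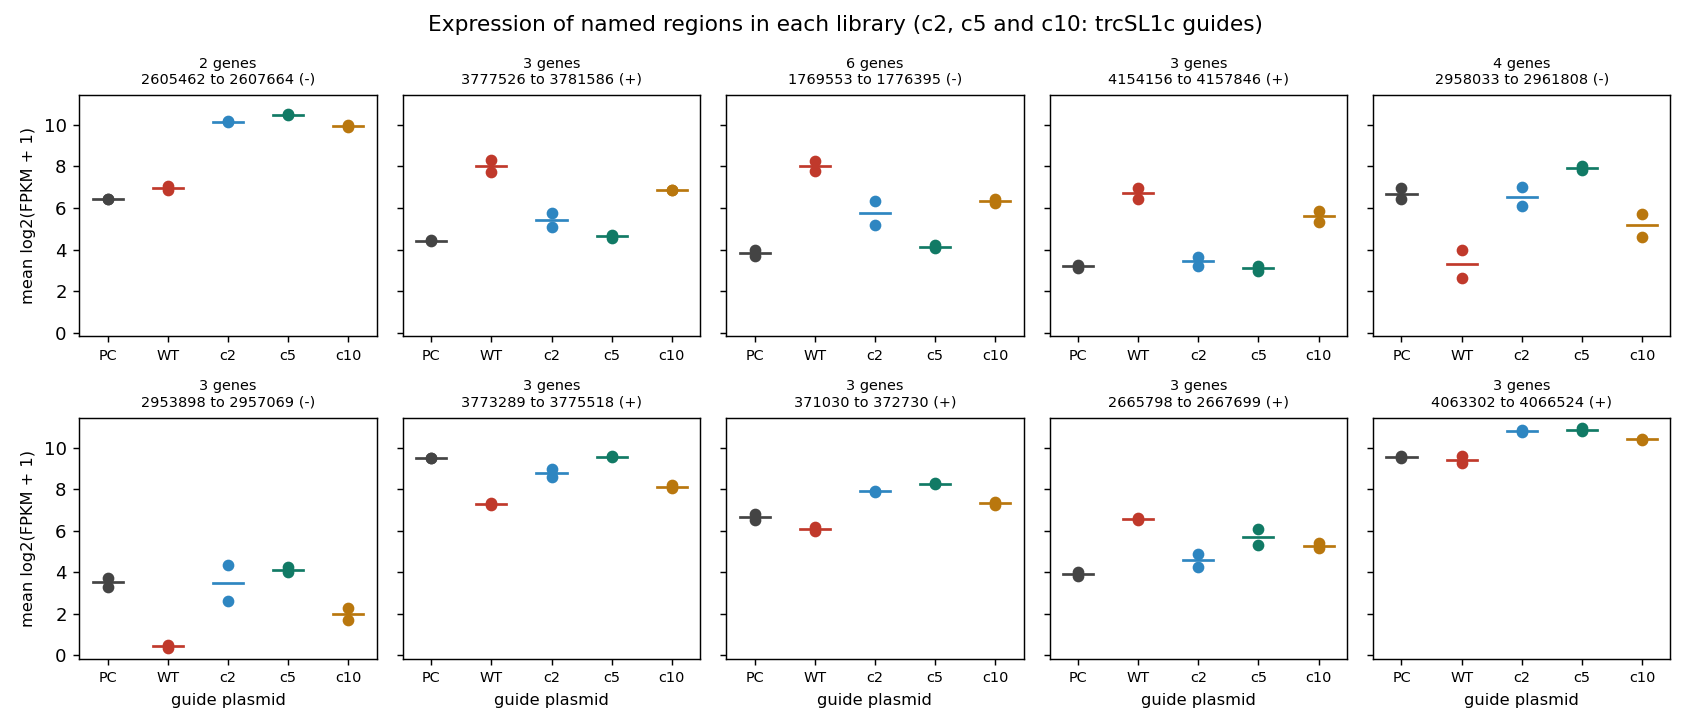
Mean log2(FPKM + 1) of 10 named regions in each library, with points for libraries and a line for the mean of 2 libraries. Titles give the number of genes, the coordinates on CP001509.3 and the strand. The 2 genes at 2605462 to 2607664 are higher in the 3 trcSL1c groups, and the 6 genes at 1769553 to 1776395 are highest in sg_WT.

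Against sg_WT, sg_trcSL1c2 showed the minus-strand regions at 2958033 to 2961808 and 2953898 to 2957069 higher, by medians of 3.26 and 3.17. A region of 4 genes at 4417118 to 4419000 was higher by 2.76. Regions at 2713355 to 2716297, 4154156 to 4157846 and 4149998 to 4153791, of 3 genes each, had medians of -3.89, -3.53 and -3.51. ECD_02826 had 104 ± 54.8 FPKM in sg_trcSL1c2 and 5.16 ± 4.74 in sg_WT (limma adjusted p = 0.00340), and ECD_02952 168.7 ± 58.9 against 9.03 ± 5.58 (limma adjusted p = 0.000276). ECD_02600 had 21.7 ± 15.0 against 426 ± 189 FPKM (limma adjusted p = 0.000316) and ECD_04056 35.6 ± 12.7 against 632 ± 77.8 (limma adjusted p = 9.50e-05). With a pseudocount of 5 the region at 2953898 to 2957069 changed by 1.81. In total 858 genes were higher and 906 lower, and 762 changed at least 2-fold.

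Between sg_trcSL1c5 and sg_WT, 940 genes were higher and 950 lower, and 900 changed at least 2-fold. The region at 2958033 to 2961808 was higher by a median of 4.53, that at 2953898 to 2957069 by 4.03 and that at 371030 to 372730 by 2.38. With a pseudocount of 5 the region at 2953898 to 2957069 changed by 2.12. The region at 1769553 to 1776395 had a median of -4.27 and that at 3777526 to 3781586 of -4.23. A region of 3 genes at 4190664 to 4194783 had a median of -3.61. In the region at 1769553 to 1776395, ECD_01715 and ECD_01716, which share reads, changed by -4.43 and -4.36. The 1 gene there that shares no reads changed by -0.96. In the region at 3777526 to 3781586 the 3 genes changed by -0.77, -4.23 and -5.15. ECD_02826 had 255 ± 8.09 against 5.16 ± 4.74 FPKM (log2 change 5.63, SE 0.79, limma adjusted p = 0.000692). ECD_03593 had 13.01 ± 2.52 against 518 ± 224 (log2 change -5.15, SE 0.36, limma adjusted p = 4.31e-05). ECD_01717 had 12.7 ± 0.45 against 464 ± 132 (log2 change -5.05, SE 0.37, limma adjusted p = 5.45e-05).

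Between sg_trcSL1c10 and sg_WT, 279 genes were higher and 325 lower, and 228 changed at least 2-fold. A region of 6 genes at 4333179 to 4340598 was higher by a median of 2.08, and regions at 4460915 to 4464628 (3 genes) and 3759234 to 3763956 (5 genes) by 1.91 and 1.72. The regions at 2713355 to 2716297, 2719740 to 2724059 and 2411075 to 2417026 had medians of -2.92, -2.56 and -2.003, the last -1.33 among its genes that share no reads. ECD_01017 had 1655 ± 103 FPKM in sg_trcSL1c10 and 101 ± 52.4 in sg_WT (log2 change 4.13, SE 0.38, limma adjusted p = 0.000699). The total of 604 became 378 or 317 without sg_WT replicate 1 or 2, 270 or 301 without sg_trcSL1c10 replicate 1 or 2, and 365 with only the groups compared in the fit.

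A block of 36 tested genes at 748484 to 790570, with locus tags from ECD_10001 to ECD_10058, was lower in each trcSL1c guide than in sg_WT. Its median log2 change was -0.87 in sg_trcSL1c2, -1.19 in sg_trcSL1c5 and -1.01 in sg_trcSL1c10, with 22, 23 and 23 genes lower past the threshold and 1 higher in each. Of 3831 windows of as many tested genes elsewhere, 0 had a median as low in each of the 3 comparisons. Against sg_PC the medians were -0.54, -0.71 and -0.67, with 9, 14 and 14 genes lower and 2, 0 and 0 higher, and 0, 0 and 17 windows were as low. These lower calls were 8, 11 and 12 of 19 minus-strand genes and 1, 3 and 2 of 17 plus-strand genes. Medians were -0.66, -0.82 and -0.77 on the minus strand and -0.20, -0.39 and -0.48 on the plus strand. Against sg_WT the lower calls were 11, 12 and 11 on the minus strand and 11, 11 and 12 on the plus strand. In sg_WT against sg_PC the block median was 0.53, with 12 genes higher and 2 lower past the threshold, and 3771 of the 3831 windows had a median at or below it. Of the block's 36 genes, 13 shared no reads with an overlapping gene, and no tested gene lay between 771313 and 788125. The block was chosen after its values were seen. It holds the regions at 754495 to 756145 and 758657 to 759786 and the gene ECD_10018 given above.

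**Figure D4:**
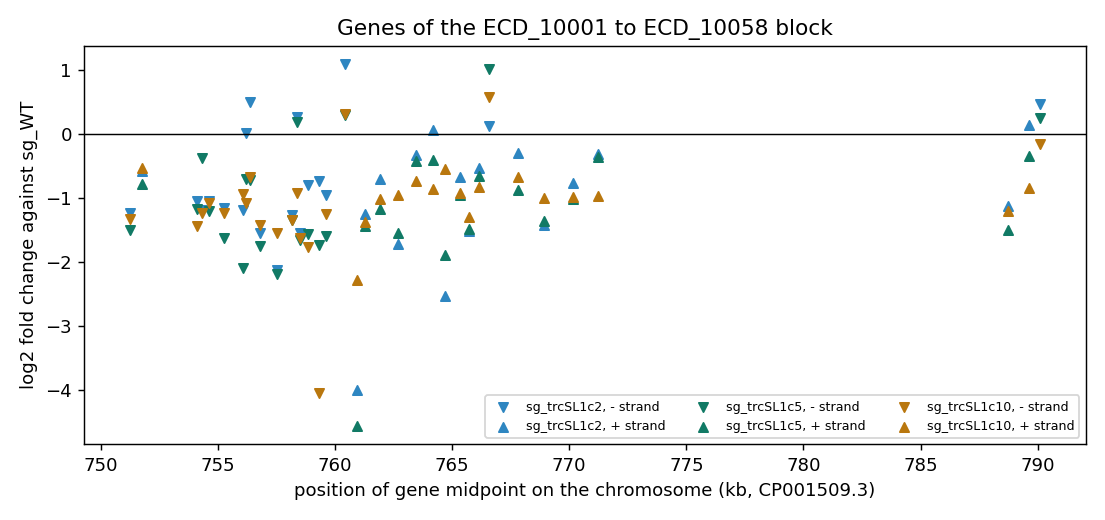
Log2 fold change of 36 genes of the block at 748484 to 790570 against sg_WT, by gene midpoint in kb, for the 3 trcSL1c guides and both strands. Medians are -0.87, -1.19 and -1.01, and a few genes lie above 0.

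The 4 comparisons against sg_PC share its libraries. Between sg_WT and sg_trcSL1c10, each against sg_PC, 365 genes were higher in both, against 89.9 for independent lists, and 384 lower in both, against 97.0. The correlation across genes was 0.71, and 0.49 in 20 simulations of unchanged groups. The covariance was 0.45 against 0.07 simulated. For sg_trcSL1c2 and sg_trcSL1c5 against sg_PC, 251 genes were higher in both, against 63.2, and 293 lower, against 72.6, with a correlation of 0.61 against 0.48 simulated and a covariance of 0.32 against 0.07. For sg_trcSL1c2 and sg_trcSL1c10 the correlation was 0.56 against 0.48 and the covariance 0.28 against 0.07. In the other 3 pairs the correlation lay below the simulated one, at 0.34 against 0.48 for sg_WT and sg_trcSL1c2, 0.19 against 0.49 for sg_WT and sg_trcSL1c5, and 0.36 against 0.49 for sg_trcSL1c5 and sg_trcSL1c10. Their covariances were 0.24, 0.13 and 0.17, each against 0.07. The simulated groups held noise only, whereas changes in a single group widen the spread of the data and lower the correlation. A correlation below the simulated one therefore does not mean that fewer changes were shared. With 2 control libraries each part of a split would hold 1, so the controls were not split, and part of the excess may come from them.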

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

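The tests of gene length, of shared reads, of the choice of groups, of the whole block and of short RNA were chosen only after the results were seen.

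Rows of tRNA genes, outside every comparison, held signal above the limit of 3 fragments that a count of 0 allows. In sg_PC replicate 1 they had 135 implied fragments, the highest of the 10 libraries, and in sg_trcSL1c2 7.99 and 9.99. Between 4 and 12 of the 85 rows were above 0 in a library. Per 1000000 implied fragments they had 14.5 ± 3.50 in sg_PC, 5.76 ± 2.36 in sg_WT, 4.05 ± 0.70 in sg_trcSL1c10, 2.13 ± 0.20 in sg_trcSL1c5 and 1.20 ± 0.16 in sg_trcSL1c2 (SD, n = 2). tRNA rows held 48.1% and 48.6% of the FPKM sum in sg_PC and 12.4% to 29.1% elsewhere. In the sg_PC libraries the same rows held only 0.0017% and 0.0012% of implied fragments, so the FPKM share does not measure an amount of tRNA. Loss of short RNA in the other libraries stays open. The median log2 change of other genes under 200 bp against sg_PC, as a mean over the 4 other guides, was 0.0125 (75 genes). By guide, genes up to 300 bp had medians of -0.21 in sg_trcSL1c2, -0.22 in sg_trcSL1c5, -0.14 in sg_trcSL1c10 and -0.02 in sg_WT. Genes over 1000 bp had 0.11, 0.09, 0.05 and -0.03 in the same order. Short genes may be read as parts of longer transcripts, so these values decide nothing. The guide group, as a biological difference, was not tested.

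In the 3 trcSL1c groups, 34 genes differed from both sg_PC and sg_WT in all 6 comparisons, 18 higher and 16 lower. Of the 16 lower genes, 7 lie in the block at 748484 to 790570, so this set and the block are not separate results. The count of 34 became 17 or 19 without sg_PC replicate 1 or 2, 17 or 18 without sg_trcSL1c10 replicate 1 or 2, and 16 with only the groups compared in the fit. The count of 34 does not stand out: 4 of the 10 choices of 3 groups, this one included, gave at least as many. The others among these 4 gave 121, 148 and 150. Against a trend with gene length, 25 of the 34 genes stayed past the threshold in all 6 comparisons once it was removed. The other 9 kept their direction, but the median of their smallest log2 change went from 0.45 to 0.37 (median SE 0.13) and so fell short. As to shared reads, 25 of the 34 genes shared none with an overlapping gene. Of all 3937 tested genes 2747 shared none, a like share, so most lists of genes would give such a count. It therefore speaks only for those 25 genes and decides nothing for the set. The 2 adjacent genes at 2605462 to 2607664 kept log2 changes of at least 2.71 after removal of the length trend, and 2 of 2 shared no reads. Both are over 1000 bp long, a class with medians of only 0.05 to 0.11 in the same 6 comparisons. Removal of so small a trend could not have undone changes of this size. In sg_WT these genes were also higher than in sg_PC, past the threshold, by smaller log2 changes of 0.36 and 0.67. The guide as a cause stays open and untested.

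The block at 748484 to 790570 was lower in the trcSL1c groups than in sg_WT. The difference holds a higher level in sg_WT too, since against sg_PC the block median was 0.53 in sg_WT and -0.54, -0.71 and -0.67 in sg_trcSL1c2, sg_trcSL1c5 and sg_trcSL1c10. Gene length is argued against, since the median nearest to 0 over the 3 guides was -0.80 with the length trend removed. The trend itself was small, so its removal could shift the block only a little. Over all genes up to 300 bp, medians against sg_WT were -0.21 in sg_trcSL1c2, -0.20 in sg_trcSL1c5 and -0.17 in sg_trcSL1c10. A single change of the whole block, such as DNA copy number, may be a source and stays open. At least 77.8% of its genes lay below 0 in each comparison with sg_WT, between the bounds set for and against it. Against sg_PC, where most of the lower calls were on the minus strand, that share was not tested. The guide group was not tested as a cause.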

How the results depend on the processing

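Alternatives added after the data were seen were those on gene length and shared reads. Under the 12 settings that keep all libraries, counts stayed within 1.5 times, except with only the 2 groups compared, which gave 599 genes for sg_trcSL1c2 against sg_PC and 365 for sg_trcSL1c10 against sg_WT. That fit has fewer samples to estimate the spread. Among genes sharing no reads fewer were tested, and counts were 0.73 to 0.78 of the main ones. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.18 to 0.12 over 10 pairs of groups, with 1 above 0.1. With a replicate block the counts were 1571 for sg_WT against sg_PC and 521 for sg_trcSL1c10 against sg_WT, and no count moved by over 1.5 times. Without scaling, sg_trcSL1c10 against sg_PC had 544 genes higher and 364 lower.

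Leaving out a library leaves 1 in its group, which is assumed to vary like the others. Beyond 1.5 times, counts moved without either sg_PC library (sg_trcSL1c2, sg_trcSL1c5 and sg_trcSL1c10 against sg_PC), either sg_trcSL1c5 library (sg_trcSL1c5 against sg_PC), either sg_trcSL1c10 library (sg_trcSL1c10 against sg_PC and sg_WT) and either sg_WT library (sg_trcSL1c10 against sg_WT). The cause was not tested beyond the loss of a sample. Counts then ranged from 1172 to 1668 for sg_WT against sg_PC, 698 to 1169 for sg_trcSL1c2, 300 to 971 for sg_trcSL1c5 and 372 to 996 for sg_trcSL1c10 against sg_PC. Against sg_WT they ranged from 1265 to 1694, 1436 to 1935 and 270 to 697 in the same order. The number of genes that differed among the 5 groups ranged from 1947 to 2268. Over these and the other settings, genes chosen for printing kept their direction in all 610 values, 599 past the threshold and 11 not. Those 11 were of ECD_03485, ECD_10018, ECD_01871 and ECD_02826. No region, block or 2-gene median changed sign, but 86 of 923 region values, 9 of 66 block values and 13 of 154 values of the 2 genes moved by at least the SD between replicates. Block medians against sg_WT ranged from -1.49 to -0.67 and moved among genes sharing no reads and without either sg_WT library. The set of 34 genes ranged from 16 to 45 over other settings, and from 17 to 38 without a library. Count tests, and tests of the gene lists and the target gene, were not run, since the files hold no counts, gene names or plasmid genes. For a region near 0 the fold depended on the pseudocount and the weights. The region at 2953898 to 2957069 in sg_WT against sg_PC had a median of -1.52 with a pseudocount of 5 and -4.98 with precision weights. Depth as a limit on such folds was not tested.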

Other observations

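Compared with sg_PC, 126 genes were higher in both sg_WT and sg_trcSL1c5, against 86.4 for independent lists, and 176 lower in both, against 94.7. Another 181 moved in opposite directions, as many as the 181 for independent lists. Of them, 101 were lower in sg_WT and higher in sg_trcSL1c5, against 87.6, and 80 went the other way. Both lists share the sg_PC libraries, which by itself moves them the same way, with a correlation of 0.49 in simulations of unchanged groups. The numbers for independent lists are therefore not a chance level for either direction.

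Among the trcSL1c guides, 595 genes differed between sg_trcSL1c2 and sg_trcSL1c5, 649 between sg_trcSL1c2 and sg_trcSL1c10, and 1172 between sg_trcSL1c5 and sg_trcSL1c10, at a limma adjusted p below 0.05. These comparisons were added after the data were seen.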
